A study of Caenorhabditis elegans with 2 samples.

How the data were processed

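The samples were 2 biological replicates of a TF ChIP-seq experiment against DPL-1 in mixed-sex L1 larvae of strain YL448, per the labels, with chromatin fragmented by sonication. Both were placed in 1 group from the description in their labels, and replicate numbers were those in the labels. Control libraries, alignments and signal tracks were not analysed here.

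The authors deposited peak lists in narrowPeak format on builds ce10 and ce11. Per the file descriptions deposited with the samples, the replicate lists came from each replicate's alignment and a control, the pooled list from both alignments and a control, and the IDR list from the pooled and replicate lists. The aligner, the peak caller and their versions were not given in the sources used here. The authors' signal per peak is on a scale that the deposited files did not state, and it was used here only to rank, describe and select peaks within a list and to set matched peaks of the replicates side by side. The -log10 q of each peak, as deposited by the authors, reached a maximum of 3.64 that 2162 peaks of the pooled ce11 list shared, so it was not used for ranking. The IDR list was the 3726 pooled peaks with the highest signal. Since pooled signal was near the sum of the replicates' signals, the values were read as not scaled to depth. The number of reads per library was not given in these lists, so no interval for sequencing depth was made, and intervals given here cover counting of peaks or genes alone.

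Main results used ce11, whose chromosomes are those of the reference WBcel235, and the Ensembl annotation of that assembly. Each of 19973 protein-coding genes had promoter windows from 500 bp upstream to 200 bp downstream of its annotated transcript starts, 29314 positions in all. A gene was called bound when an IDR summit lay in a window, and it took the signal of its strongest such peak. Summits outside promoters were put in exons, introns or intergenic sequence, in that order. Peaks were matched between lists when summits lay within 100 bp, and the match with the highest signal was taken where there were several. Lists of 1999 gene symbols or family members, of which 8 did not match the annotation by current or older symbol, were fixed before the data were examined. They covered DNA replication and G1/S, mitosis, DNA repair, DREAM and synMuv regulators, germline P granule and small RNA genes, meiosis, intestine, neurons, body muscle, epidermis, ribosomal proteins, the proteasome, histones and chemoreceptors. Genes named in the text were those whose promoters held the 20 strongest IDR peaks, up to 4 bound members of each list with the highest signal, and dpl-1, efl-1, lin-35, lin-54, ges-1, elt-2 and unc-119. Gene classes by name stem were chosen after the data were seen.

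Counts per chromosome and per feature were tested with exact binomial tests against the share of the genome, and gene lists with Fisher's exact test against all other protein-coding genes. Median log2 signal was compared with permutation tests of 100000 resamples for lists with 5 or more bound members. Strings were searched on both strands within 50 bp of each summit and in a window centred 500 bp to the lower coordinate, and compared with exact McNemar tests. All tests were two-sided, adjusted by the Benjamini-Hochberg method within each family at 0.05. Intervals of shares are exact Clopper-Pearson 95% intervals, and those of string ratios come from 1000 bootstrap draws of summits. Correlations across peaks had permutation p-values from 100000 pairings. The chance level of matching came from 100 random placements.

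Alternatives set before the data were examined were the stronger 1863 IDR peaks, each replicate alone with its 3726 strongest peaks, merged peaks, ce10 lists, other rules of overlap, promoters from 1000 bp upstream, nearest start within 1000 bp, a background of genes with a three-letter name, genes whose promoters overlap no other, the mean of replicate ranks, windows of 100 bp and other control windows. Alternatives added afterwards were chance from peaks of the other replicate, expected counts by genes, autosomal genes alone, a background of genes with a three- or four-letter name, promoter summits alone, and the order of genes by mean rank. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

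The code was tested on simulated data. Simulated lists of 50 genes with 70 or 40% of members bound passed the threshold in 20 of 20 runs for gene list occupancy among 19973 genes, and lists bound like other genes in 2 of 20. For list signal among 2800 simulated genes, a 4-fold shift passed in 20 of 20 runs and no shift in 0 of 20. Matching recovered 71.0% of 3726 peaks when 70.9% had been shifted by under 100 bp.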

Results

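Binding of DPL-1 to the genome was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in first-stage (L1) larvae of the nematode Caenorhabditis elegans. DPL-1 is the worm's DP protein, the partner of E2F transcription factors and a member of the DREAM complex, which represses cell cycle genes. The strain carried a transgene in which the promoter of ges-1, an intestinal esterase gene, drove DPL-1 fused to GFP and FLAG tags, beside a copy of unc-119 that rescues the strain's unc-119 mutation. Whole larvae were used, so chromatin of every tissue was in the sample. The antibody label named dpl-1 and the epitope was not given in the sources used here, so it was unknown whether the peaks came from native DPL-1 of all tissues, from the intestinal transgene product or from both. The series held 1 group of 2 biological replicates. No condition was compared with another, and the results below describe where peaks lay, which genes they lay beside and how far the replicates matched. Each replicate had a list of 30000 peaks without a threshold, as did the pooled data. The list passing the authors' irreproducible discovery rate (IDR) threshold held 3726 peaks on build ce11. Read totals were not given in the peak lists, so the depth behind each peak was unknown, and peaks, genes and summits were not replicates, so p-values describe these lists.

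The strongest DPL-1 peaks lay nearly all at promoters, among them those of ribosomal protein genes and of efl-1. The highest signal, 5289, was at III:3867380-3867761, with its summit 290 bp upstream of rpl-3 (WBGene00004414), which codes for a protein of the large ribosomal subunit. This peak ranked 1 in replicate 1 and 2 in replicate 2. It was followed by cdc-48.1 (signal 5125, II:10563396-10563765), an AAA ATPase that unfolds ubiquitinated proteins, by citk-2 (signal 4787) and by the ribosomal protein gene rpl-35 (signal 4038). The promoter of efl-1, the E2F partner of DPL-1, held the peak of rank 6 (V:16965661-16966020, signal 3429), with its summit 168 bp upstream of the transcript start, and it ranked 6 in replicate 1 and 25 in replicate 2. Among the 20 strongest peaks, 19 lay in promoters. The others of them were those of eelo-2, the mitochondrial enzyme gene dld-1, the translocon subunit gene sec-61.G, rbd-1 with its divergent neighbour T23F6.3, the mitochondrial import gene ddp-1, tasp-1, the cytochrome c oxidase gene cox-5A, the alpha-tubulin gene tba-2, the splicing factor gene syf-3, C27F2.9, fbxl-2, F48A11.4, Y53F4B.9 with Y53F4B.11, and pafo-1, of the PAF1 complex. The peak of rank 20 was intergenic, at I:16856-17195. Peaks of the IDR list had signals from 39.5 to 5289 (median 94.0), a median width of 320 bp, and together covered 1.05% of the genome.

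The same strong promoters stood out in both replicates, and weaker peaks were shared less. The peaks at rpl-3, cdc-48.1 and citk-2 took the first 3 ranks in each replicate. Of the 3726 strongest peaks of replicate 1, 2509 (67.3%) had a summit within 100 bp among the 3726 strongest of replicate 2. Random positions on the same chromosomes gave 0.826% ± 0.133 (SD over 100 draws), and 3726 peaks drawn from all 30000 of replicate 2, a background chosen after the data were seen, gave 10.3% ± 0.465. The share was 91.8% for the strongest 500 peaks, 88.0% for the strongest 1000 and 81.8% for the strongest 2000. Nearly all IDR peaks (99.5%) had a match in the list of replicate 1 and 87.1% in that of replicate 2. For replicate 2 this was 98% of the stronger 1863 IDR peaks and 76.2% of the weaker ones. Over the 3231 IDR peaks matched in both lists, log2 signals correlated across peaks with a Pearson r of 0.911 and a Spearman rho of 0.854 (permutation p = 1e-05 for each, the smallest that 100000 pairings can give). The IDR list was itself made from these replicates and unmatched peaks were left out, so some agreement was built in. Signal was 5.32 times as high in replicate 1 as in replicate 2 at the median peak (10th to 90th percentile 3.30 to 10.7), and the pooled signal was close to the sum of the 2 (median ratio 1.00, 5th to 95th percentile 0.948 to 1.07), so replicate 1 made up 84.2% of it at the median peak.

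**Figure D1:**
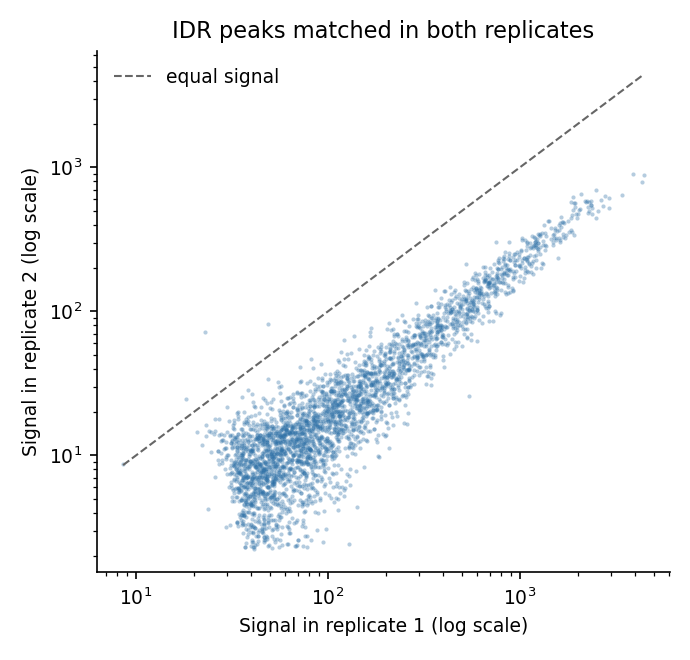
Signal of the 3231 IDR peaks matched in both replicates, replicate 1 on the x axis and replicate 2 on the y axis, both on log scales and in the authors' signal units. Each point is 1 peak and the dashed line marks equal signal. Nearly all points lie below the line, at a median ratio of 5.32.

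DPL-1 peaks were concentrated on chromosomes III and I and were sparse on chromosome X. Chromosome III held 743 IDR peaks, 53.9 per Mb, and chromosome I held 756, 50.2 per Mb, against 396 peaks, 22.3 per Mb, on X. Relative to chromosome length the observed count was 1.45 times the expected one on III (adjusted p = 8.0e-25, exact binomial test), 1.35 times on I (1.4e-17) and 0.601 times on X (2.9e-32), or 0.361 times among the stronger 1863 peaks. Chromosome V, where chemoreceptor genes are most numerous, had 580 peaks, 0.746 times the expected count (3.0e-16), and IV had 611, 0.940 times (0.092). Chromosome II had 640, 1.13 times the expected count (0.0014), but 1.02 times without replicate 1 (0.63) and 0.995 times when expected counts followed protein-coding genes in place of length. By the same gene-based expectation X had 0.777 times the expected count and V, then the lowest, had 0.623 times. Per gene, 221 of 2731 protein-coding genes on X (8.09%) had a bound promoter, against 2631 of 17242 on the autosomes (15.3%, odds ratio 0.489, 95% interval 0.422 to 0.565, p = 5.5e-26 by Fisher's exact test, two-sided). On build ce10 the authors' IDR list held 3761 peaks, with 748 on III and 401 on X.

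Peaks lay mostly at promoters, upstream of transcript starts, and rarely in exons. Promoters, taken as 500 bp upstream to 200 bp downstream of protein-coding transcript starts, held 2262 summits, or 60.7% (95% exact interval 59.1 to 62.3%), 3.71 times their share of the genome (16.4%). Introns held 490 summits (13.2%, 0.444 times their share, 0.270 times among the stronger 1863 peaks) and intergenic sequence held 921 (24.7%, 0.826 times, adjusted p = 1.5e-12 by the exact binomial test, 0.536 times among the stronger peaks). Exons held 53 (1.42%), 0.0591 times their share, which became 0.261 times without replicate 1 and 0.0312 times among the stronger peaks. Promoter summits lay at a median of -154 bp from the nearest transcript start (quartiles -251 and -72 bp), and 92.6% were upstream of it. Promoter peaks were also the stronger ones, with a median signal of 136 against 65.6 in introns and 69.1 in intergenic sequence. In 5 groups of equal size from the strongest to the weakest IDR peaks, the share in promoters was 91.2, 68.3, 54.8, 47.9 and 41.3%.

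Summits also lay often near small noncoding RNA genes. Of the IDR summits, 244 (6.55%) lay within 200 bp of a tRNA, snoRNA, snRNA or rRNA gene, 12.3 times the share of the genome so covered (p = 1.3e-173, exact binomial test), or 7.94 times among the stronger 1863 peaks. Transfer RNA genes accounted for 135 summits (13.3-fold, adjusted exact p = 5.6e-100), snoRNA genes, whose products guide RNA modification, for 88 (13-fold, 6.9e-65) and snRNA genes of the spliceosome for 22 (9.01-fold, 3.7e-14). No summit was near the 20 annotated rRNA genes. The comparison was with the whole genome and left overlap with promoters aside. Highly transcribed loci can give ChIP signal of any factor, so whether these summits mark binding of DPL-1 was not settled.

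Cell cycle, ribosomal protein and proteasome genes were bound far more often than other genes, and chemoreceptor genes far less often. Lists of intestine, neuron and epidermis genes were also bound less often, but these calls depended on the rules used. An IDR summit lay in the promoter of 2852 of 19973 protein-coding genes (14.3%), and 640 peaks lay in promoters of 2 or more genes. Of these genes 81.3% were also bound in the list of replicate 2 alone, cut at the same number of peaks, and 97.4% in that of replicate 1 alone. The second share was largely built in, since replicate 1 made up 84.2% of the summed signal at the median peak. Among 14 gene lists fixed before the data were examined, 11 differed from other genes (Fisher's exact test, two-sided, Benjamini-Hochberg adjusted over the lists), and 7 did so with nearest starts, 7 on promoters that overlap no other and 8 on autosomes. The odds ratio is given below as the size of each difference.

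DNA replication and G1/S genes were bound at 38 of 49 promoters (77.6%, 95% exact interval 63.4 to 88.2%, odds ratio 21, adjusted exact p = 1.2e-22). The strongest were pcn-1, the replication clamp PCNA (rank 38, signal 2293, IV:4049534-4049913), orc-5 of the origin recognition complex (rank 77, signal 1654), cdl-1, the histone mRNA stem-loop binding protein (rank 93), and the clamp loader subunit rfc-4 (signal 1487). Mitosis and chromosome segregation genes were bound at 48 of 69 (69.6%, interval 57.3 to 80.1%, odds ratio 13.9, adjusted exact p = 1.1e-24), with odds ratios from 6.6 with each peak given to its nearest start alone to 25.7 with promoters from 1000 bp upstream. They were led by topoisomerase II, top-2 (rank 41, signal 2205), the kinetochore gene knl-3 (rank 64), cyclin B, cyb-1, which shares its peak with orc-5, and separase, sep-1 (rank 143). The summit of the shared peak lay at -498 bp from the start of cyb-1, near the edge of the window. In replicate 2 the peak had rank 105 with its summit at -506 bp, so cyb-1 was not called bound without replicate 1. DNA repair genes were bound at 30 of 52 (57.7%, interval 43.2 to 71.3%, odds ratio 8.26, adjusted exact p = 9.5e-13), with the translesion polymerase polh-1 (rank 60), the checkpoint genes mrt-2 (rank 127) and chk-1 (rank 207) and the nuclease fan-1 (rank 146) the strongest.

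Genes of the DREAM complex and of synMuv chromatin regulators, the class that holds dpl-1 itself, were bound at 14 of 32 promoters (43.8%, interval 26.4 to 62.3%, odds ratio 4.69, adjusted exact p = 0.00011). The odds ratio was 8.03 with promoters from 1000 bp upstream. Besides efl-1, they included lin-54 (rank 110, signal 1445), the DNA-binding subunit of DREAM, lin-9 (rank 145), the histone chaperone gene lin-53 (rank 178) and lin-35 (rank 301, signal 772), the worm's retinoblastoma protein. Germline P granule and small RNA genes were bound at 18 of 71 (25.4%, odds ratio 2.05, adjusted exact p = 0.027), led by mes-2, an H3K27 methyltransferase (rank 46), simr-1 (rank 185), tost-1 (rank 422) and mrg-1 (rank 484). That difference was lost against genes with a three-letter name (odds ratio 1.32, adjusted exact p = 0.42), of which fewer entered the list, and against those with a three- or four-letter name (1.53, 0.14). It was also lost with nearest starts (1.51, adjusted exact p = 0.30) and on promoters that overlap no other (1.83, 0.22). Meiosis genes, at 9 of 45 (20%, odds ratio 1.5, adjusted exact p = 0.31), did not pass the threshold, and their odds ratio was 2.92 on promoters that overlap no other. Their strongest bound members were rec-1, pch-2, cmt-1 and brd-1.

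Cytosolic ribosomal protein genes had the highest share of any list, 66 of 76 (86.8%, interval 77.1 to 93.5%, odds ratio 40.5, adjusted exact p = 1.3e-44). With each peak given to its nearest start alone their share was 52.6% (odds ratio 7.56), below replication genes at 69.4% and the proteasome at 66.7%. After rpl-3 and rpl-35, the strongest were rpl-24.2 (rank 23) and rps-12 (rank 57). Proteasome subunits were bound at 26 of 33 (78.8%, interval 61.1 to 91.0%, odds ratio 22.5, adjusted exact p = 4.1e-16), with the deubiquitinase subunit rpn-11 (rank 109), pbs-1 (rank 285), pas-5 (rank 318) and rpn-5 (rank 323) at the top. Their odds ratio ranged from 13.5 with nearest starts to 35.1 with promoters from 1000 bp upstream. Histone genes were bound at 11 of 82 (13.4%, odds ratio 0.930, adjusted exact p = 1), but on promoters that overlap no other at 4 of 16 (odds ratio 3.66, adjusted exact p = 0.069). The strongest was the variant histone gene htz-1 (rank 155), followed by his-37 (rank 408) and by the peak shared by his-67 and his-68 (rank 1225).

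Intestinal genes, of the tissue in which the ges-1 promoter is active, were bound at 5 of 83 promoters (6.02%, interval 1.98 to 13.5%, odds ratio 0.384, adjusted exact p = 0.035). The strongest of these were erm-1, which links membrane and actin (rank 1285), the nuclear receptor genes nhr-49 (rank 1548) and nhr-80 (rank 2139), and hgo-1 of tyrosine breakdown (rank 2516). Neither the nhr-80 nor the hgo-1 peak had a match in the list of replicate 2. Without replicate 1, hgo-1 was still called bound and nhr-80 was not. No peak of the pooled list lay in the promoter of elt-2, the GATA factor of the intestine (WBGene00001250, X:10481240-10483441), and the promoter window of ges-1 held only a pooled peak of rank 14761. An IDR peak of rank 766 lay just outside that window, with its summit 546 bp upstream of ges-1, a locus that the transgene also carries in part. Neuron markers were bound at 2 of 52 (3.85%, odds ratio 0.240, adjusted exact p = 0.035), namely ric-19 (rank 156) and snb-1 (rank 1130), and epidermis and cuticle markers at 2 of 51 (3.92%, odds ratio 0.244, adjusted exact p = 0.035), namely bli-6 (rank 551) and col-10 (rank 3392). These 3 differences rested on few bound genes and no longer passed on the fewer genes whose promoters overlap no other (odds ratio 0.496 and adjusted exact p = 0.30 for intestine, 0.243 and 0.23 for neuron, 0.266 and 0.30 for epidermis). With all genes kept and each peak given to its nearest start they were lost too (0.715 and adjusted exact p = 0.60 for intestine, 0.268 and 0.092 for neuron, 0.274 and 0.092 for epidermis). The intestine difference was further lost with promoters from 1000 bp upstream (0.510, adjusted exact p = 0.092), and all 3 on autosomal genes alone (0.495, 0.317 and 0.2997), an alternative chosen after the data were seen. Among the stronger 1863 peaks the neuron and epidermis differences did not pass (0.387 and 0.193), and the intestine difference did (0.238, adjusted exact p = 0.035). The neuron difference was also lost without replicate 1 (odds ratio 0.271, adjusted exact p = 0.075), where the epidermis odds ratio was 0.136. Body muscle markers, at 3 of 43 (6.98%, odds ratio 0.450, adjusted exact p = 0.31), did not pass the threshold (odds ratio 0.230 among the stronger peaks and 0.883 with nearest starts), and those bound were unc-45 (rank 354), unc-112 (rank 2104) and unc-60 (rank 3032). The unc-60 peak had no match in the list of replicate 1, though unc-60 was still called bound without replicate 2. Chemoreceptor genes were bound at 6 of 1253 promoters (0.479%, interval 0.176 to 1.04%, odds ratio 0.0268, adjusted exact p = 7.2e-75). Their odds ratio was 0.0407 without replicate 1 and 0.0430 with promoters from 1000 bp upstream. The strongest of these were srh-16 (rank 29), sri-5 (rank 67), srd-4 (rank 226) and srh-2 (rank 1268).

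**Figure D2:**
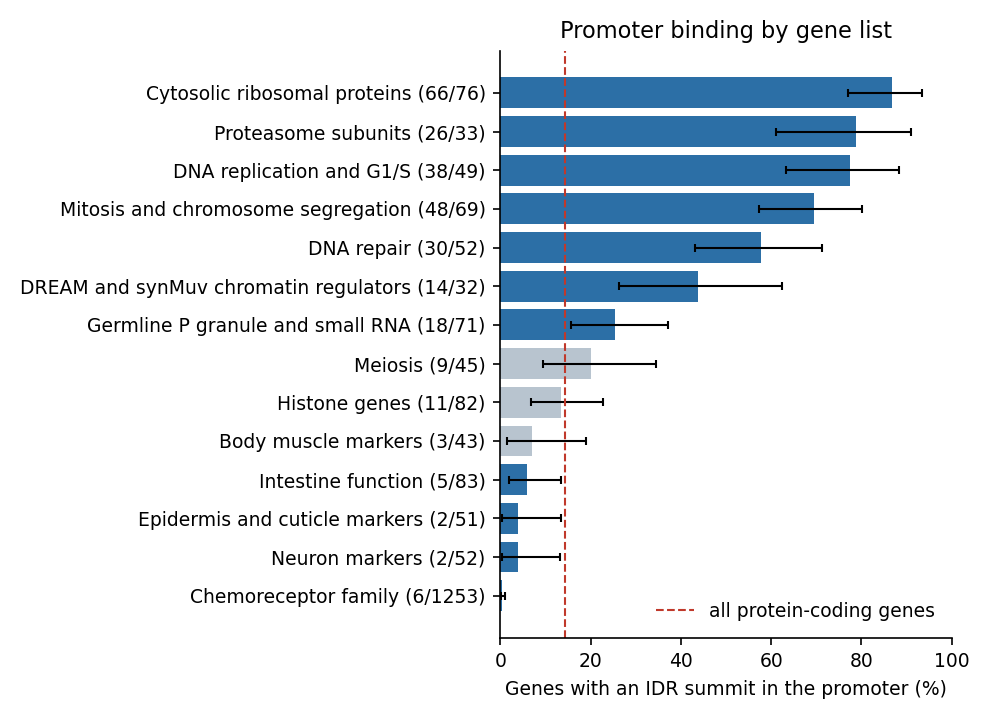
Percent of the protein-coding genes of each list with an IDR summit in the promoter, with 95% exact binomial intervals as error bars and bound over measured genes beside each name. The dashed line is the share of all protein-coding genes, 14.3%, and dark bars are lists with an adjusted p under 0.05. Ribosomal protein genes reach 86.8% and chemoreceptor genes 0.479%.

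Cell cycle genes also carried the stronger of the promoter peaks. Bound replication genes had a median signal of 615, 4.08 times that of other bound genes (difference 2.03 on the log2 scale, adjusted p = 0.00022, permutation test, two-sided). The median was 3.35 times as high for bound DREAM and synMuv genes (adjusted p = 0.013), 2.29 times for mitosis genes (0.0026), 2.24 times for ribosomal protein genes (0.00094) and 2.03 times for DNA repair genes (0.035), each by the same permutation test. When genes were compared by the mean of their ranks in the 2 replicates instead of the pooled signal, none of these 5 differences passed the threshold (adjusted permutation p = 0.063 for replication and ribosomal protein genes, 0.082 for mitosis, 0.17 for DREAM and repair). The medians of the other lists tested did not pass it with either measure. Those with pooled signal were 1.86 times for germline genes (adjusted permutation p = 0.18), 1.09 times for meiosis (0.89), higher by 0.32 on the log2 scale for the proteasome (0.54), 0.511 times for intestine (0.39), 0.506 times for histones (0.20) and 2.47 times for chemoreceptors (0.18).

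The E2F/DP recognition sequence was frequent at bound replication and mitosis promoters and close to its level in control windows at ribosomal protein promoters. The string TTSSCGC (S being C or G) lay within 50 bp of the summit at 22 of 38 bound replication promoters (57.9%, interval 40.8 to 73.7%), against 3 in windows 500 bp away (adjusted p = 0.00015, exact McNemar test), and at 28 of 48 mitosis promoters (58.3%), against 5 (0.00015). At ribosomal protein promoters it lay at 4 of 63 summits (6.35%), against 3 in control windows (adjusted exact p = 1), and at proteasome promoters at 7 of 26 (26.9%), against 1 (0.25). DNA repair promoters had it at 6 of 29 summits (20.7%), against 2 (adjusted exact McNemar p = 0.61). DREAM and synMuv promoters had it at 2 of 14 (14.3%), against 0. The share over all promoter summits was 17.5%, and no list but replication and mitosis passed the threshold. At the pcn-1 summit the string was TTCGCGC, at IV:4049654-4049660 in intergenic sequence, within ATGAAACTTCGCGCCTCAATT. The shared peak of orc-5 and cyb-1 held TTCGCGC on the minus strand at IV:10734755-10734761, also intergenic, and the knl-3 peak held TTGGCGC at V:1868807-1868813, in an exon. Neither the rpl-3 nor the efl-1 summit had the string.

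Over all IDR summits, TTSSCGC was present at 585 of 3726 (15.7%, interval 14.5 to 16.9%) against 4% of control windows, a 3.93-fold difference (95% bootstrap interval 3.34 to 4.69, adjusted p = 2.2e-67, exact McNemar test), or 5.89-fold against unbound promoters. Its reversed string CGCSSTT, a control of the same base composition, was rarer, at 8.59%, but differed from its control windows by as much, 4.78-fold (interval 3.70 to 6.20). Against unbound promoters the reversed string was 5.74-fold. The cell cycle homology region TTYGAA (Y being C or T), bound by LIN-54, was less frequent at summits than in control windows (28.5% against 32.0%, 0.891-fold, adjusted exact p = 0.0016). That direction turned to 1.19-fold among the stronger 1863 peaks, and without replicate 1 the value was 0.938-fold (adjusted exact p = 0.076). The reversed string of TTYGAA, of the same base composition, was depleted further, 0.428-fold (95% bootstrap interval 0.378 to 0.486, against 0.833 to 0.953 for TTYGAA). TTYGAA was thus less depleted than its control of base composition, so its lower frequency does not show that the site was avoided. The GATA site TGATAA of intestinal factors was at 5.56% of summits against 9.42% of control windows (0.590-fold, adjusted exact p = 2.0e-10, 0.299-fold among the stronger peaks), and its reversed string at 6.39% against 6.82% (0.937-fold, 0.49). In the 5 groups from strongest to weakest peaks, TTSSCGC was present at 29.2, 17.9, 12.1, 9.80 and 9.53% of summits.

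**Figure D3:**
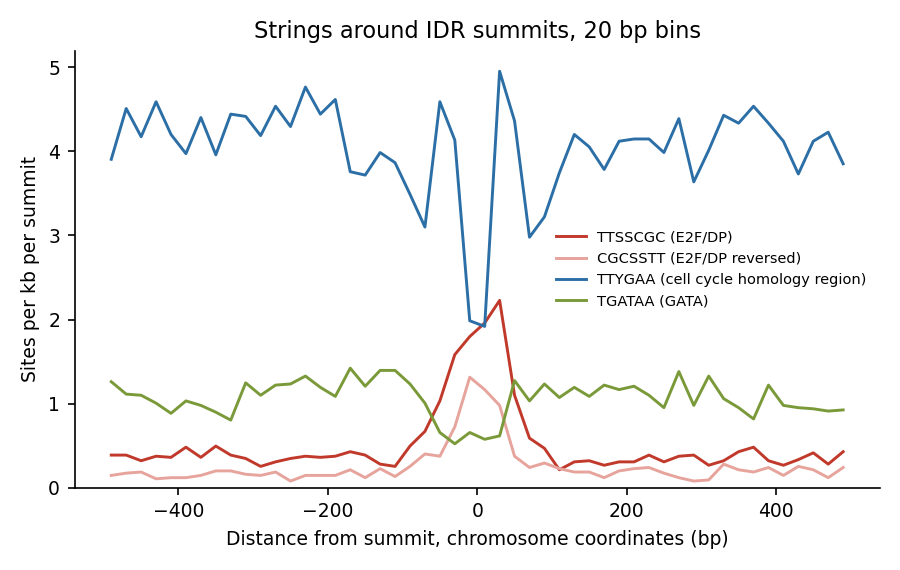
Number of strings per kb per summit in bins of 20 bp around the 3726 IDR summits, by distance in chromosome coordinates in bp. Each line is 1 string, with the reversed E2F/DP string as a control of base composition. TTSSCGC reaches 2.23 sites per kb at 30 bp, and TTYGAA falls to 1.92 at 10 bp.

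The loci carried by the transgene held peaks of middle rank, some of them inside gene bodies. The unc-119 gene (III:10902641-10908935) held 4 IDR summits, all in the gene body, 2 in introns and 2 in exons. The summit of rank 2931 lay 46 bp past an annotated internal transcript start. The strongest, at III:10905251-10905409, had rank 1242 and signal 158. The peak at this site ranked 1060 in replicate 1 and 961 in replicate 2, whose own strongest unc-119 peak, of rank 506, lay at another site in an exon (III:10907889-10908097). The native promoter of dpl-1 (II:9169910-9172565) held a peak of rank 675 with signal 340, at II:9169544-9169741, which ranked 638 in replicate 1 and 879 in replicate 2. Its summit, 269 bp upstream of dpl-1, also lay in an annotated exon outside that gene. A further dpl-1 peak of rank 3096 lay in an intron, and in replicate 2 alone 4 peaks lay in the dpl-1 gene body. Upstream of ges-1 (V:1427653-1432137) a peak of rank 766 with signal 289 lay at V:1432523-1432842, its summit 546 bp upstream of the gene and outside the promoter window, and this region ranked 751 in replicate 1 and 822 in replicate 2. Extra copies of these sequences in the strain were not measured here.

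**Figure D4:**
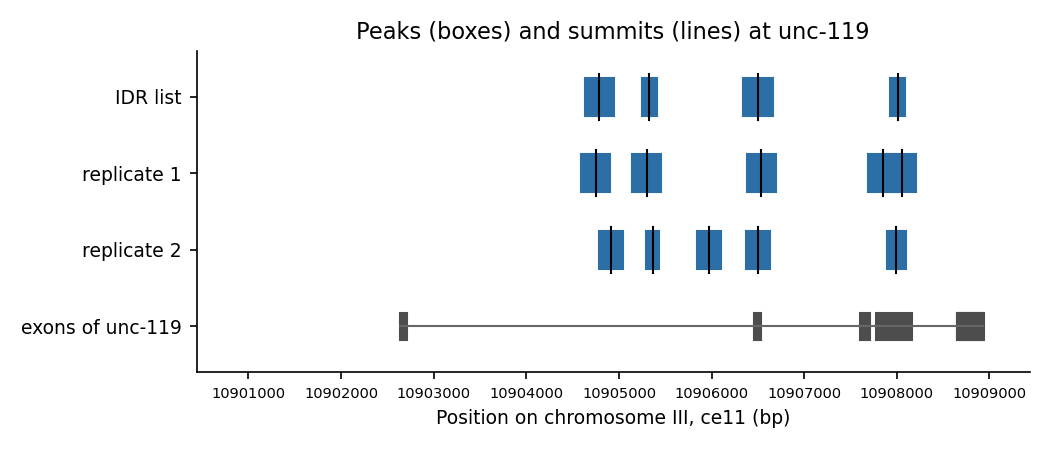
Map of the unc-119 gene on chromosome III, build ce11, with positions in bp on the x axis. Boxes are peaks and lines their summits in the IDR list and among the 3726 strongest peaks of each replicate, above the annotated exons. The IDR list has 4 peaks in the gene body and each replicate has 5.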

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

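All tests in this part were chosen after the lists had been seen. The pooled peaks just below the IDR threshold, ranks 3727 to 7452, were used in no comparison above and were flagged because the E2F/DP string was more frequent at their summits than in control windows. TTSSCGC lay at 7.35% of these 3726 summits and at 4.19% of control windows (1.76-fold, exact McNemar p = 3.8e-09). The reversed string CGCSSTT rose as well, from 1.64 to 3.6% (2.20-fold, exact McNemar p = 1.1e-07), so the rise was not particular to the E2F/DP string. Of these summits 32.4% were in promoters. No biological explanation was tested.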

How the results depend on the processing

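The order of genes by mean rank, the expected counts by genes, chance from the other replicate's peaks, the autosomal genes alone, the background of three- or four-letter names and the promoter summits alone were chosen after the data were seen. Of 266 alternative values of the main results, 226 kept their direction and side of the threshold or stayed within the spread allowed. The cause of the other changes was not tested, except that fewer peaks or genes enter some of them. The stricter threshold left 1863 IDR peaks by construction, and 1869 genes were bound by them. Replicate agreement was 70.7% with any overlap, 61.5% with reciprocal overlap and 83.8% in the top 1863, and chance was 10.3% from the other replicate's peaks. Chromosome II ranged from 1.02 to 1.14 times the expected count without each replicate and reversed to 0.995 by genes.

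The number of lists past the threshold fell from 11 to 7 with nearest starts and to 7 with promoters that overlap no other. Odds ratios that no longer passed were as follows. Germline genes had 1.51 with nearest starts, 1.32 against genes with a three-letter name, 1.53 with four-letter names added and 1.83 with promoters overlapping no other. Intestine had 0.510 with promoters from 1000 bp, 0.715 with nearest starts, 0.496 with promoters overlapping no other and 0.495 on autosomes, and still passed at 0.238 in the stronger 1863 peaks. Neurons had 0.387 in the stronger 1863 peaks, 0.271 without replicate 1 (0.239 without replicate 2, which still passed), 0.268 with nearest starts, 0.243 with promoters overlapping no other and 0.317 on autosomes. Epidermis had 0.193, 0.274, 0.266 and 0.2997 under the stronger peaks, nearest starts, promoters overlapping no other and autosomes.

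For list signal, the alternative set before the data were examined was the mean of the 2 replicate ranks. Under it all 5 list differences were lost, with median differences of 924 rank positions for replication, 671 for mitosis, 599 for repair, 825 for DREAM and 638 for ribosomal proteins. Ordering genes by that mean, a choice made after this loss had been seen, gave adjusted permutation p-values of 0.00011, 0.0031, 0.038, 0.024 and 0.0020 for the same lists, so it is no independent check.

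TTYGAA reversed to 1.19-fold in the stronger 1863 peaks and to 1.07-fold at promoter summits, ranged from 0.900 to 0.938 without each replicate and was 0.947 with controls at the higher coordinate. The reversed GATA string passed at 0.764-fold against unbound promoters. The best rank was 506 for unc-119, 879 for dpl-1 and 822 for ges-1 in replicate 2's own list. Without replicate 1, 3 of 72 named genes (col-10, cyb-1 and nhr-80) had no promoter peak among the 3726 strongest. The replicate 2 summit was in the promoter at rank 19398 for col-10 and just outside it, at -506 bp and rank 105, for cyb-1, and nhr-80 had no match. Without replicate 2 none was lost, which was largely built in, since 95.5% of IDR peaks matched the 3726 strongest peaks of replicate 1. The same limit holds for the other values without replicate 2. Leaving out a replicate fixed the number of peaks, so it gave no peak count, and replicate agreement needs both. Gene results were not run on ce10, and its chromosome shares used ce11 lengths. Depth was unknown, so its effect on the weaker peaks was not measured.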

Other observations

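The gene classes by name stem, the transgene tests, the separate tests of ribosomal protein and proteasome summits, the tests of the reversed string at replication and mitosis promoters and the count of chemoreceptor genes on chromosome X were chosen after the results were seen. Among 175 classes with at least 10 members, 25 were bound more often and 29 less often than other genes (Fisher's exact test, Benjamini-Hochberg adjusted). Beyond the lists above, the translation initiation factors eif- were bound at 19 of 25 promoters (adjusted exact p = 2.7e-10), the nuclear pore proteins npp- at 19 of 26 (6.9e-10), and the mitochondrial ribosomal proteins mrpl- at 23 of 41 (1.1e-08) and mrps- at 16 of 29 (4.8e-06). The Integrator subunits ints- and the RNA polymerase II subunits rpb- were each bound at 9 of 11 (1.2e-05). So were the cyclin-dependent kinases cdk-, some of which were already in the replication and mitosis lists. Secretory genes sec- reached 12 of 19 (1.5e-05), vesicle sorting genes vps- 15 of 31 (6.4e-05) and the proton pump vha- 10 of 20 (0.0011).

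Of the 29 classes bound less often, 15 were stems of the chemoreceptor family. Among the others, the F-box genes fbxa- were bound at 12 of 170 promoters (adjusted exact p = 0.021) and none of the 37 math- genes was. C-type lectins clec- were bound at 5 of 240 promoters (adjusted exact p = 4.7e-09), collagens col- at 7 of 156 (0.00093) and neuropeptides nlp- at 1 of 71 (0.0025). None of the 58 transthyretin-like ttr-, 56 ligand-gated channel lgc- and 38 insulin-like ins- genes was bound. TTYGAA had a profile with a dip at the summit, 1.99 and 1.92 sites per kb at -10 and 10 bp, between local maxima of 4.59 at -50 bp and 4.95 at 30 bp. The value at -50 bp was within the range seen farther away, where it reached 4.76 at -230 bp.

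The string TTSSCGC lay at 11 of 89 bound ribosomal protein and proteasome summits and at 49 of 85 replication and mitosis summits (odds ratio 0.104, 95% interval 0.0439 to 0.234, Fisher's exact p = 2.0e-10). By share of summits, this is what a weaker tie to the factor's own sequence at the first set would give. The 2 lists in that set were unlike, with an odds ratio of 0.0498 (0.0123 to 0.156, Fisher's exact p = 2.4e-11) for ribosomal protein summits and 0.271 (0.0875 to 0.770, 0.0073) for proteasome summits. Whether there was signal at active promoters without the factor's own sequence cannot be told apart from a small excess of the string, since few summits or control windows held it. Its share was 1.33 times that of control windows at ribosomal protein summits (4 against 3, exact McNemar p = 1), 7 times at proteasome summits (7 against 1, p = 0.070) and 2.75 times in both together (p = 0.092). At replication and mitosis summits the ratio was 6.125, so by this measure, on few counts, proteasome summits were not lower.

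Base composition of promoters may account for the excess over all summits, where the reversed string rose as much (4.78-fold). At replication and mitosis promoters 42 summits held TTSSCGC alone and 4 the reversed string alone, against 298 and 171 at the other promoter summits (odds ratio 6.03, 95% interval 2.13 to 23.5, Fisher's exact p = 6.0e-05). TTSSCGC thus outnumbered its reversed string by more at these summits than at the other promoter summits. Whether base composition gave its rise over control windows there was not settled, since 8 of those windows held TTSSCGC and 1 the reversed string. The reversed string was about as frequent at replication and mitosis summits (12.9%) as at ribosomal protein and proteasome summits (13.5%), while TTSSCGC was at 57.6 and 12.4%. An argument against base composition at first also required a larger rise over control windows for TTSSCGC than for the reversed string. This condition was not met and was then replaced by a looser one. The looser one asked only that the reversed string's rise not exceed that of TTSSCGC by more than their 95% bootstrap intervals. The reversed string rose from 1 to 11 of 85 summits (95% bootstrap interval 2.5 to 17-fold) and TTSSCGC from 8 to 49 (3.42 to 15.7-fold), so that comparison rested on 1 control window and decided nothing.

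The transgene loci held summits inside gene bodies, outside every promoter window. Extra copies of the transgene may account for the 3 such IDR summits in unc-119, a number reached by 0.0329% of 3041 genes of like length, and for the 4 in replicate 1 and 3 in replicate 2. That share was 1 gene, which may be unc-119 itself, and was the same in both replicates' lists. Binding in the annotated promoter windows alone would not give these summits. The count took only summits outside those windows, after they had been seen, so it is no independent test of promoter binding. For dpl-1, extra copies of the transgene and promoter binding alone cannot be told apart, since it had 1 such summit, a number reached by 1.51% of 6971 genes of like length, with 0 in replicate 1 and 4 in replicate 2. The control libraries that would show copy number were not analysed here, and no biological explanation was tested.

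Chromosome X held fewer peaks. Fewer genes on X may account for part of this, since its count was 0.601 times that expected by length and 0.777 times that by genes. As the whole cause it is argued against. It would leave the share of bound genes equal, but the odds ratio per gene was 0.489 (95% interval 0.422 to 0.565). Silent chemoreceptor genes are argued against as well, since the family made up 31 of 2731 genes on X (1.14%) and 1222 of 17242 on the autosomes (7.09%, odds ratio 0.151, 95% interval 0.102 to 0.215, Fisher's exact p = 3.2e-45). No biological explanation was tested.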
